A study of Homo sapiens with 6 samples.

How the data were processed

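Total RNA of 92.1 uveal melanoma cells was extracted with TRIzol and a column kit, and libraries were made and sequenced by a company, per the labels' protocols. Cells had been treated with 1 µM VS-4718 or DMSO for 2 h, with 3 libraries in each group. Kallisto, without a version, and the build GRCh38 are named in the submitters' processing notes; the index, the annotation, the library's strandedness and any filters are not given in the sources used here. The deposited values are log2 expression per gene symbol. That they are log2 of a TPM-like value follows from the values: put back on the linear scale, the columns of the deposited table sum to between 836527 and 840714, so that 15.9% to 16.3% of a full TPM total lies outside the rows. Every one of the 12306 rows had a finite value in every library, and between 19.4% and 19.9% of the values lay below 1 on the TPM-like scale. The lowest value was -27.80, so some rows had been given a value next to nothing. TPM keeps no depth, so no counting interval can be given.

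Row names were matched to human genes through the reference tables: 9351 carried a current human symbol, 284 a human synonym that belongs to a single gene, and 2671 had no match. The names follow mouse usage (clone names, GM numbers, H2 and ZFP genes, pseudogene suffixes), while the sources name GRCh38. Which transcripts the reads were matched to is not given in the sources used here. If they were mouse transcripts, a human transcript that differs from its mouse counterpart, or resembles a mouse pseudogene, would be counted low or in another row; rows of gene families are uncertain in any case. Coordinates are those of the matched human genes in GENCODE 29 (GRCh38) and were used for location only.

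The main test was limma 3.58.1 in R 4.3.3 (limma-trend: a linear model of the values as given, with group as the only term, and empirical Bayes variances that follow the mean). Rows with a mean above the lowest 25% were kept, which left 9229 rows with a mean over 0.70. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are differences of mean log2 values, VS-4718 minus vehicle, with limma's moderated SE. With 3 libraries against 3, an exact permutation of a single gene cannot go below a p of 0.1, so single genes were tested only in the model across all genes. A first fit had also used limma's robust variances, which the design foresaw for linear values only; the design's wording for log values was then followed, and both fits called the same 12 rows.

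Gene lists (40 lists, 965 genes, of which 667 had a row) were fixed before the data were examined, as were the design, the rule for naming genes and the other settings to be tried, except those named below as added. The 32 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over those 32. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it. Genes were named by this rule: among rows past the threshold whose groups did not overlap and whose higher group mean was at least the median of tested means (3.99), up to 12 in each direction; PTK2, PTK2B, YAP1, WWTR1, CCN1, CCN2, ANKRD1, AMOTL2 and LATS2 in any case; and up to 4 members with the smallest p of each list past its test and of the YAP/TAZ, immediate early, ERK, SRF/MRTF and melanocyte lists. ANKRD1 had no matching row among those used here. A gene that this rule selects is not reported here. PMEL, SOX10, MLANA, DCT, GAPDH, ALDOA, COX4I1, ATP5B, RPLP1, CRIM1, EGFL7, PECAM1, DDIT3, ATF4, the SR protein and CLK genes that were not called and the mitochondrial rows were named outside that rule, after their values were seen.

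The script was tested on simulated data with 9229 genes and the real spreads, 200 of them changed. It recovered 32.8% of genes changed by 0.5 log2 units, 67.2% of those changed by 1 and 93.9% of those changed by 2, with 8 false calls beside 129 true ones. A simulated fall of 1 log2 unit in the YAP/TAZ list was called, with 1 other list called beside it. Alternatives were a replicate block, each library left out in turn, median scaling between libraries, no filter, a stricter filter, limma without trend, sample quality weights and a minimum change of 1.2-fold. A pseudocount of 1, rows with human names only and robust variances were added after seeing the data. Figures were drawn with matplotlib 3.10.9.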

Results

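RNA was sequenced from 92.1 cells, an established human uveal melanoma line, after 2 h with VS-4718 or with DMSO vehicle. VS-4718 is a small-molecule inhibitor of focal adhesion kinase (FAK, encoded by PTK2) and was given at 1 µM. Each group held 3 libraries. The design text calls them independent samples and they were taken as replicates; the labels do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The deposited table held 12306 gene rows with a log2 value per library. The values are log2 of a TPM-like measure (transcript abundance scaled to a fixed total), which keeps no read total, so the depth of each library is unknown. Rank correlations (Spearman, across genes) lay between 0.985 and 0.988 for libraries of the same group and between 0.984 and 0.988 across groups.

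Some genes of the melanocyte lineage had high values in both groups and others were nearly missing. PMEL, a melanosome matrix protein, stood at 12.21 ± 0.07 (SD, n = 3) log2 units in vehicle and 12.24 ± 0.09 with VS-4718. SOX10, a transcription factor of the lineage, stood at 8.20 ± 0.04 and 8.17 ± 0.04. MLANA, a melanosome protein, stood at -1.82 ± 1.02 and -1.24 ± 1.04, and DCT, a melanin enzyme, at 0.63 ± 0.06 and 0.39 ± 0.17. The row names were mouse gene symbols in capitals, although the labels give a human line and a human genome build. Of the rows, 9635 had a name that matched a human gene and 2503 had a name of a purely mouse style. The mouse-style rows held between 42.8% and 44.0% of the summed values of a library. Some abundant genes were nearly missing: GAPDH, a glycolytic enzyme, had 0.604 TPM-like units, while ALDOA of the same pathway had 1690. A level therefore describes a row of this table, and comparisons are made within a row.

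The first comparison asked which transcripts differed after 2 h with VS-4718, and 12 rows passed. Percent changes below are ratios of geometric means. CLK1 rose by 1.11 log2 units (SE 0.11, adjusted p = 0.028) and CLK3 by 0.81 (SE 0.09, adjusted p = 0.045); both encode kinases that phosphorylate SR proteins, a family of splicing factors. SRSF3 and SRSF7 encode SR proteins. SRSF3 fell by 31.7%, from 10.28 ± 0.05 (SD) to 9.73 ± 0.04 log2 units (adjusted p = 0.014), and SRSF7 fell by 42.0%, from 6.43 ± 0.12 to 5.65 ± 0.04 (adjusted p = 0.023). CYR61 (CCN1), a secreted matrix protein and a target of the YAP and TAZ coactivators, fell by 38.8% (adjusted p = 0.023). MAT2A, the enzyme that makes S-adenosylmethionine, fell by 32.3%, from 6.14 ± 0.02 to 5.58 ± 0.02. PDK4, a kinase that restrains pyruvate dehydrogenase, was 75.9% higher, from 7.60 ± 0.09 to 8.42 ± 0.08. E2F3, a cell cycle transcription factor, rose by 1.25 (SE 0.14) and ZC3H10 fell by 0.75 (SE 0.09), each with an adjusted p of 0.045.

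In all, 12 of 9229 tested rows passed the limma test with Benjamini-Hochberg adjustment, 4 higher and 8 lower with VS-4718. The 3 not yet named carry mouse-style names, GM12355 (which fell by 35.9%), GM18821 (which fell by 41.2%) and RPL34-PS2 (which fell by 71.1%); which human transcripts fed them is not known, and they may share reads with related genes. In each of the 12 the treated and vehicle values did not overlap. Across all tested rows 1510 did not overlap (16.4%, against 10% by chance), and 901 had an unadjusted limma p under 0.05. Of the 901, 622 were lower with VS-4718 and 279 higher. The median log2 fold change of all tested rows was -0.03, so lower rows outnumbered higher ones. Numbers of lower genes in the lists below are to be read against that. Leaving out a library changed the count of called rows more than the fold changes. Over the alternatives these ran from -0.58 to -0.52 for SRSF3 and from 0.76 to 0.86 for PDK4. The count was 0 without vehicle replicate 1 (763 rows at an unadjusted p under 0.05), 7 without vehicle replicate 2 (5 of them among the 12), 0 without vehicle replicate 3 (764), 1 without VS-4718 replicate 1, 0 without VS-4718 replicate 2 (706) and 0 without VS-4718 replicate 3 (990). It was also 0 with the planned replicate block (793 rows at an unadjusted p under 0.05). The count was 0 as well in limma without the mean-variance trend (910) and against a minimum change of 1.2-fold (146).

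**Figure D1:**
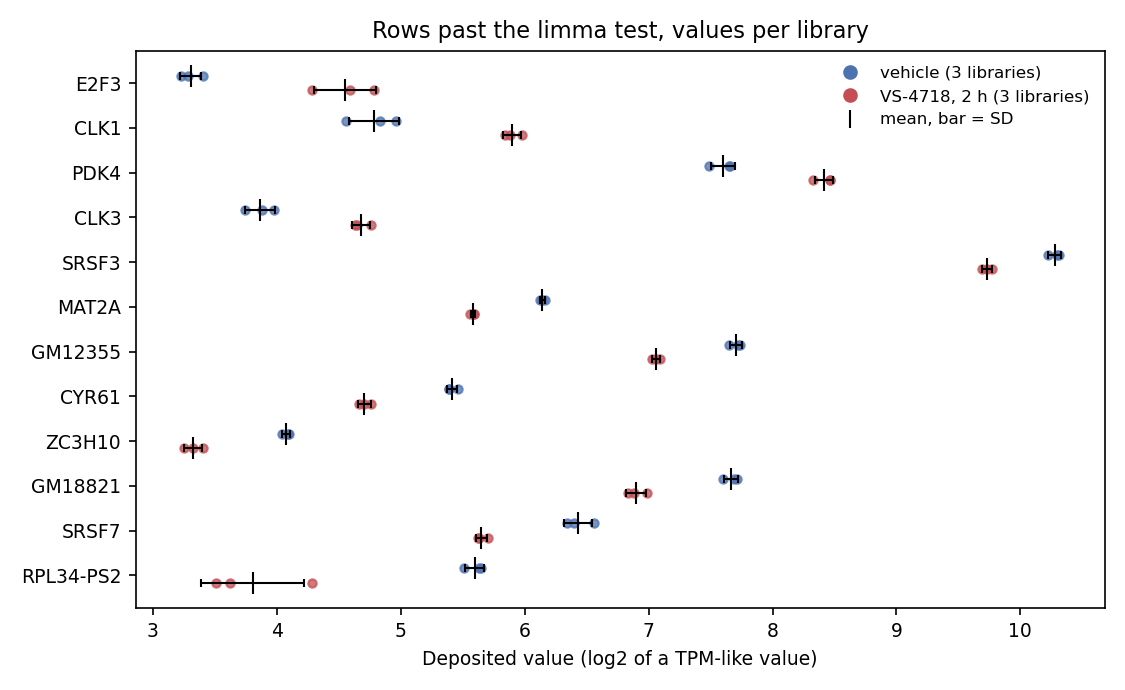
Deposited values (x axis, log2 of a TPM-like value) of the 12 rows past the limma test (y axis), with points for each of 3 vehicle and 3 VS-4718 libraries, vertical marks for means and bars for SD. E2F3, CLK1, PDK4 and CLK3 lie higher with VS-4718, and the other 8 rows lie lower, with no overlap between groups.

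In GENCODE 29 on GRCh38, the human genes matched to these rows are all protein coding; the values are per gene and cover no particular exon. CCN1 lies on chromosome 1 from 85580761 to 85583962, and MAT2A on chromosome 2 from 85539165 to 85545280. SRSF7 is on chromosome 2 from 38743599 to 38751494 and CLK1 on the same chromosome from 200853009 to 200864744. SRSF3 spans 36594353 to 36605600 and E2F3 20401906 to 20493715, both on chromosome 6. PDK4 lies on chromosome 7 from 95583499 to 95596491, ZC3H10 on chromosome 12 from 56118159 to 56127514 and CLK3 on chromosome 15 from 74598500 to 74645414.

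The second comparison asked whether target genes of YAP and TAZ, the coactivators that the Hippo pathway restrains, moved with VS-4718. As a list they were lower: 10 of the 11 tested genes had a lower mean with VS-4718, with a mean log2 fold change of -0.38 and a median of -0.30 (camera, adjusted p = 0.0019 over 32 lists). In camera with an estimated correlation between genes the list did not pass (adjusted p = 0.18). The estimate was -0.013, below the preset 0.01, so a larger correlation did not remove this call. CYR61 passed over all genes, from 5.41 ± 0.04 to 4.71 ± 0.05. Adjusted over the list alone, 3 genes passed: CYR61, AMOTL2, an angiomotin family member that binds YAP (log2 fold change -1.2, SE 0.24), and GADD45A, a stress-response gene (-0.30, SE 0.09). Over all genes AMOTL2 had an adjusted p of 0.22 and GADD45A one of 0.37. CTGF (CCN2), another secreted target, had a log2 fold change of -0.72 with an SE of 0.40 and LATS2 one of -0.41 with an SE of 0.29; neither passed, and over the alternatives they ran from -1.0 to -0.32 and from -0.72 to -0.22.

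**Figure D2:**
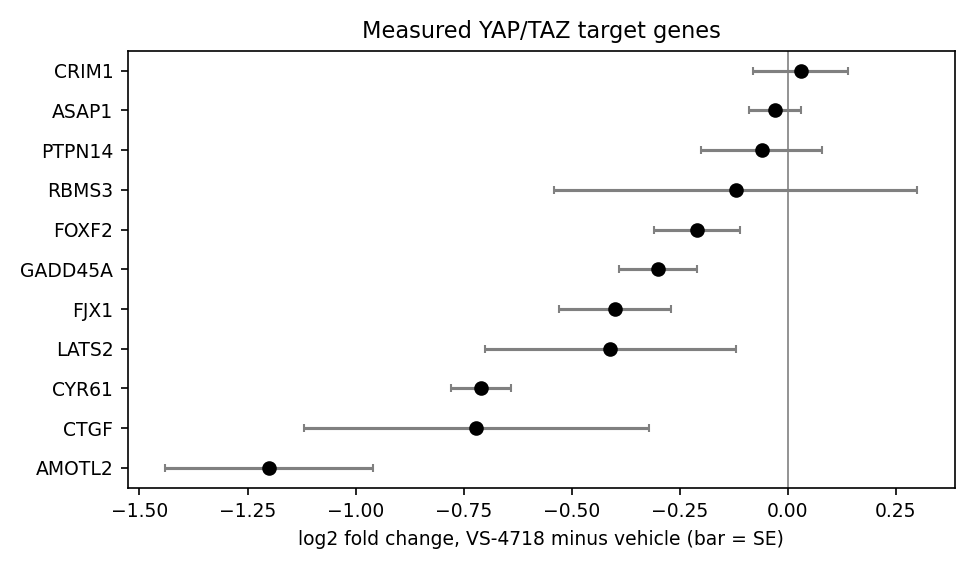
Log2 fold change of each of the 11 tested YAP/TAZ target genes (y axis), VS-4718 minus vehicle (x axis), with bars for the SE from limma. AMOTL2 (-1.2) and CYR61 (-0.71) lie well below 0, and CRIM1 (0.03) is the 1 gene above it.

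Transcripts of the drug target and of the coactivators themselves did not pass. PTK2 stood at 4.27 ± 0.41 in vehicle and 4.12 ± 0.09 with VS-4718 (adjusted p = 0.84), YAP1 at 3.32 ± 0.39 and 3.26 ± 0.04 (adjusted p = 0.94), and WWTR1, which encodes TAZ, at 4.24 ± 0.08 and 4.24 ± 0.07 (adjusted p = 0.99). The signs of these differences near 0 depended on which library was left out. PTK2B, the FAK paralog PYK2, was too low to be tested, at -1.28 ± 0.26 and -1.67 ± 0.37. Hippo pathway components had 18 of 25 tested genes lower but did not pass as a list (camera, adjusted p = 0.071); the list passed without vehicle replicate 2 (0.019), without VS-4718 replicate 1 (0.046) and with no filter (0.015). FAK and its partners had 9 of 14 lower (adjusted p = 0.97).

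Of the 32 lists tested, 7 passed camera with the preset correlation, 4 lower and 3 higher. With an estimated correlation none of the 32 passed camera, and 4 had an unadjusted p under 0.05. The estimate was below the preset 0.01 for the MYC (0.002), YAP/TAZ (-0.013), PI3K/FOXO (-0.027) and BCL2 (-0.073) lists. A larger correlation therefore did not remove those calls. It was above the preset for the ERK (0.035), ribosomal protein (0.106) and cholesterol (0.116) lists. In fry 5 lists passed: the MYC list (adjusted p = 0.03), the YAP/TAZ list (0.033) and the PI3K/FOXO, BCL2 and immediate early lists (0.042 each). The lower list with the smallest camera p held genes of MYC and ribosome biogenesis: 25 of 28 had lower means, with a median of -0.11. Its adjusted p in camera was 0.00036 with the preset correlation and 0.18 with an estimated one. None of its members passed limma over all genes; 7 had an unadjusted p under 0.05. NOP56, a core protein of small nucleolar particles, went from 7.33 ± 0.07 to 7.09 ± 0.03, and NCL, which encodes nucleolin, from 9.99 ± 0.04 to 9.86 ± 0.04. Cholesterol synthesis genes had 13 of 19 lower (adjusted p = 0.039; adjusted p = 0.48 with an estimated correlation). HMGCS1, an early enzyme of the pathway (-0.50, SE 0.09), and SQLE (-0.35, SE 0.08) were among 4 lower genes that passed adjusted over the list alone, while LSS went the other way (0.54, SE 0.13) and passed too.

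Output genes of the ERK pathway were also lower as a list, with 15 of 18 below vehicle (adjusted p = 0.039; adjusted p = 0.44 with an estimated correlation). DUSP6, a phosphatase that ERK induces and that restrains it, went from 4.86 ± 0.10 to 4.43 ± 0.11, and CCND1, which encodes cyclin D1, from 6.22 ± 0.07 to 5.94 ± 0.05; neither passed over all genes. EGR1, the member with the smallest p, went the other way (0.86, SE 0.11, adjusted p = 0.0021 over the list alone). The ERK list failed camera without vehicle replicate 1 or 3 and without VS-4718 replicate 2 or 3, and the cholesterol list without vehicle replicate 1 or 3 and without VS-4718 replicate 2, with adjusted p up to 0.16 and 0.18 over the alternatives. Both also failed camera with the replicate block (0.059 each), with the stricter filter (0.062 and 0.092) and among human names only (0.053 and 0.054). They failed fry too (0.11 and 0.10). Immediate early genes went both ways (11 of 25 lower, median 0.08, mean -0.05) and did not pass camera (adjusted p = 0.32), but passed fry as higher (adjusted p = 0.042). EGR1, also of this list, and JUN (-1.45, SE 0.18) had opposite signs, each with an adjusted p of 0.072 over all genes and 0.0015 adjusted over the list alone.

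The remaining 3 lists were higher. Genes responsive to PI3K and FOXO had 11 of 16 higher (adjusted p = 0.0019; adjusted p = 0.18 with an estimated correlation). PDK4 passed over all genes, and adjusted over the list alone 4 members rose and 2 fell, among them SESN1 (0.42, SE 0.10), CCNG2 (1.08, SE 0.32) and GADD45A. The BCL2 family had 5 of 9 higher (adjusted p = 0.014; adjusted p = 0.27 with an estimated correlation), with a median of 0.12. BMF, a BH3-only promoter of apoptosis, went from 4.39 ± 0.11 to 4.99 ± 0.09 and was the 1 member past the list's own adjustment. Without VS-4718 replicate 1 that list had an adjusted p of 0.05 and did not pass. Cytosolic ribosomal protein genes had 32 of 40 higher by small amounts, with a median of 0.06 (adjusted p = 0.00036; adjusted p = 0.44 with an estimated correlation; fry, adjusted p = 0.27). Their mean of 0.20 was raised by RPLP1, which varied between libraries by 9.88 log2 units (SD) in vehicle. RPS19, for example, went from 11.93 ± 0.03 to 12.01 ± 0.05. Ribosomal protein genes have many near-identical copies, so reads may be split among their rows.

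**Figure D3:**
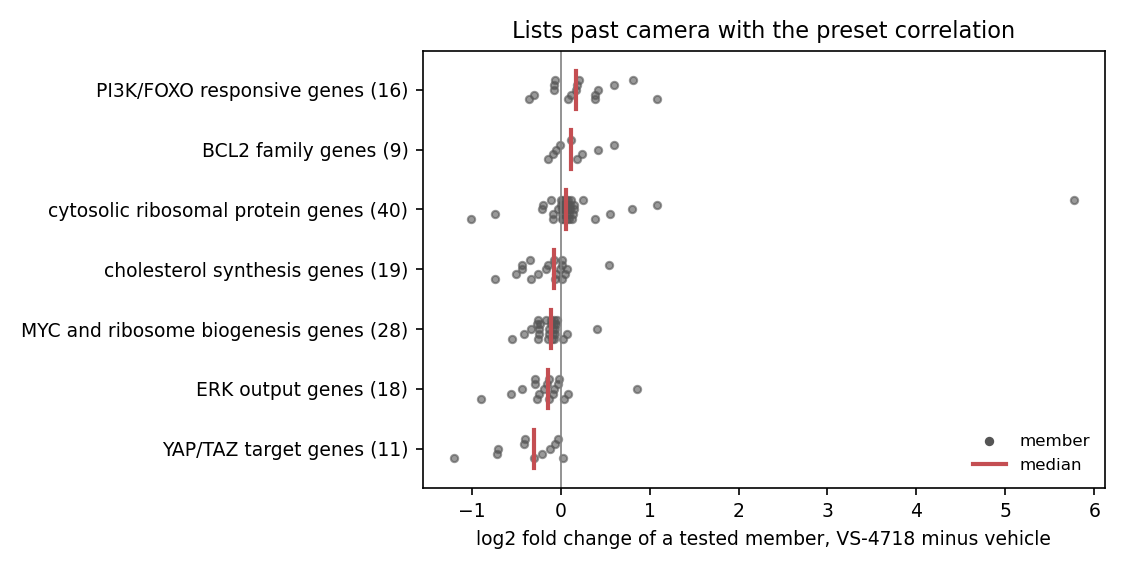
Log2 fold change of each tested member (points, x axis) of the 7 lists that passed camera with the preset correlation (y axis, number tested in brackets), with red bars for medians. Medians run from -0.30 for YAP/TAZ targets to 0.17 for PI3K/FOXO genes, and the point at 5.77 is RPLP1.

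The other 25 tested lists did not pass camera, and of them only the immediate early list passed fry. Cytoskeletal targets of SRF and MRTF had 11 of 20 lower (adjusted p = 0.67), and none of them passed over all genes; CNN2, a calponin, had a log2 fold change of 0.30 (SE 0.09) and ACTG1, a cytoskeletal actin, 0.10 (SE 0.05). Focal adhesion scaffolds (12 of 23 lower, adjusted p = 0.62), integrins (3 of 5 lower, adjusted p = 0.97) and extracellular matrix genes (5 of 10 lower, adjusted p = 0.69) went both ways. Melanocyte identity genes had 9 of 15 lower (adjusted p = 0.79); PAX3 had a log2 fold change of 0.22 (SE 0.09) and EDNRB of -0.12 (SE 0.06). Genes of G2/M had 23 of 25 lower by small amounts, with a median of -0.09 (adjusted p = 0.058); the list passed without vehicle replicate 3 (0.029), without VS-4718 replicate 1 (0.033) and with no filter (0.021). Heat shock genes (adjusted p = 0.68), ER stress genes (0.97), interferon response genes (0.55), p53 targets (0.19) and hypoxia genes (0.60) did not pass either test. Most markers of other cell types had no row among those used here, which gives no level for them: 6 of 14 fibroblast, 3 of 18 immune, 3 of 13 endothelial and 3 of 16 epithelial markers had a row. The fibroblast and immune rows were too low to test, and of the endothelial markers EGFL7 had a log2 fold change of 0.15 (SE 0.08) and PECAM1 of -0.14 (SE 0.32).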

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

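The pseudocount of 1, the restriction to human names and the robust variances were chosen after seeing the data. The count of 12 called rows was the least stable result. It was 0 with the replicate block (793 rows at an unadjusted limma p under 0.05), 0 in limma without trend (910) and 0 against 1.2-fold (146). It ran from 0 to 7 when a library was left out. The replicate block and the fits with a library less have fewer degrees of freedom, and the 1.2-fold test asks for a larger change. How far this accounts for the lost calls was not tested, nor was the cause in limma without trend. The same 12 rows were called with median scaling, the stricter filter, the pseudocount and robust variances, 11 of them with quality weights, 8 without a filter and all 9 with a human match among human names only. Same-numbered libraries had residual correlations of 0.13, 0.05 and 0.03 across genes, against -0.09 to 0.05 for the other pairs. VS-4718 replicate 3 correlated best with vehicle replicate 2. These values do not exclude pairing. The main fit kept no block because the design had set it as an alternative. The number of lists past camera was 7, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05; the other alternatives stayed within 1.5 times. The ERK and cholesterol lists lost their calls in 7 and 6 of the 12 camera alternatives, the replicate block among them (adjusted p = 0.059 each). The YAP/TAZ list kept a negative mean throughout, between adjusted p of 0.00023 and 0.014 in the 12 camera alternatives, and lost its call only with an estimated correlation (-0.38, adjusted p = 0.18). With a library left out, signs near 0 reversed for PTK2 (-0.34 to 0.07, positive without vehicle replicate 1), YAP1 (-0.28 to 0.08, positive without vehicle replicate 1 or 3) and WWTR1 (-0.04 to 0.05, negative without vehicle replicate 2 or 3 or VS-4718 replicate 1). Among named genes, 628 gene-by-setting values kept their direction and side of the threshold and 94 kept direction but lost the call. Most of the 628 come from genes that were never called and had no call to lose. All 94 belong to the 12 called rows. Each of these kept its call in only 5 to 7 of 13 or 14 settings, such as E2F3 in 5 of 14 and PDK4 in 7 of 14. The planned pseudocount of 0.1 was not run, since the values were already on a log scale.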

Other observations

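The families were chosen after the first results were seen, as were all the tests of this part except those of the SR protein genes not looked at before, of the respiratory chain rows and of the other splits. Most SR protein genes had lower means and the CLK kinase genes higher ones. Of 12 measured SR protein genes 11 were lower with VS-4718, with a mean log2 fold change of -0.31; SRSF9 was the exception at 0.04, and only SRSF3 and SRSF7 passed over all genes. All 4 CLK genes were higher, with a mean of 1.00, among them CLK2 (0.89, SE 0.18) and CLK4 (1.2, SE 0.37), which did not pass over all genes. These counts held in each of the 6 fits with a library left out and with median scaling (SR mean -0.28, CLK mean 1.04).

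One scaling factor per library would move both families alike, and the tables argue against it: the CLK mean minus the SR mean within a library, which no such factor can move, went from -3.31 ± 0.18 to -2.0 ± 0.06, a change of 1.31. No such factor can produce this change. The contrast says nothing on how far the pattern holds, since the families were picked from these values. Median shifts of the libraries were small, from -0.039 (VS-4718 replicate 2) to 0.026 (vehicle replicate 1) log2 units. A permutation over members and the calls kept with median scaling had been tried before this contrast and dropped. Whether SRSF3 shares reads with GM12355 or GM18821 was not tested and stays open. The 8 SR protein genes not looked at before the family was chosen had a mean of -0.20, with 7 lower. Their unadjusted p was 9e-04 in camera with the preset correlation, the setting without which none of the 32 lists passed camera. The pattern may belong to the family, as a hypothesis found and tested on the same libraries. Whether it came through FAK or another target of the compound was not tested.

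The mouse row names leave open what the rows count, and no biological explanation was tested. RNA of mouse cells as the source of the rows was not excluded by the test set in advance, although the labels name a human line. Mouse RNA would bring every subunit of the respiratory chain. Of 72 nuclear genes of the chain not looked at before, 38 had a row, and genes without a row were not counted. Of these 38 rows 4 (10.5%, 95% binomial interval 2.9% to 24.8%) lay below 1% of their median in all 6 libraries. Under 5% had been set in advance for mouse RNA and at least 20% against it. Rows such as GAPDH (0.604 TPM-like units) and COX4I1 (0.784) beside ALDOA (1690) and ATP5B (1490) go against it, but were picked out as low. Earlier bounds on the mitochondrial mRNA rows (10 rows, a sum of 523 to 817, nearly all MT-ND6) and on the median of other abundant genes (22.9) were dropped, the first as assumed and the second after it was missed. Human reads matched to mouse transcripts might keep genes of near-invariant proteins high and lose others of like abundance. Of 27 members in each panel, 26 near-invariant and 22 other genes had a row, and over these the medians differed by 4.30 log2 units. However, 11 of these rows had been looked at when the panels were chosen. Among them the 5 other genes had at most 5.79 TPM-like units and the 6 near-invariant ones at least 49.7. Without them the difference was 0.67 (95% bootstrap interval -2.15 to 8.43, 20 and 17 rows). This comparison cannot decide that explanation, since the interval spans both outcomes. Of the 17 other rows 6 lay below 10 TPM-like units, against none of the 20 near-invariant ones. Those 6 low rows of abundant genes also argue against mouse RNA as the source, for the genes they cover.

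Only 10 splits of the 6 libraries into groups of 3 exist, so no share under 0.05 can be reached. The real split gave 12 called rows, and 1 of the 10 splits (the real one) gave as many; the highest of the others gave 0 in limma with Benjamini-Hochberg adjustment, with 611 rows at an unadjusted p under 0.05 in the split that had the most, against 901.

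Vehicle replicate 1 had the highest values of several mitochondrial rows, such as MT-CO1 at 3.64 log2 units against 0.77 to 1.84 in the other 5 libraries. The ATF4 and amino acid response list did not pass (camera, adjusted p = 0.47), but DDIT3 (-0.65, SE 0.09) and ATF4 (-0.22, SE 0.04) passed adjusted over the list alone, with adjusted p of 0.10 and 0.18 over all genes in limma.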
